A study of Homo sapiens with 72 samples.

How the data were processed

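RNA sequencing libraries came from 72 samples of primary dermal fibroblasts treated for 6 h, made per the labels' protocols with a stranded poly(A) mRNA kit (TruSeq) from 750 ng of column-purified RNA. Per the submitters' processing notes, Salmon 1.4.0 and DESeq2 were used, the latter with no version given. The deposited values are a signal, normalised counts per gene, in which the authors' counts appear to have been divided by a single size factor per library: every library's values were whole multiples of the value of 1 read, within a tolerance of 0.01, for 100% of genes. No factor per gene was therefore applied after the counts were made whole. The pattern does not show whether the counting step corrected for length or GC content. A difference between libraries that follows GC content or RNA composition can stay in the values. The build and annotation the authors used are not given in the sources used here; coordinates and gene types printed here come from the GRCh38 annotation (GENCODE 29), matched by gene identifier. The counting tool shares reads between transcripts, so genes with near-identical copies, pseudogenes, nuclear copies of mitochondrial sequence and readthrough genes are reported as uncertain.

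The table holds 17714 genes, of which 849 have no symbol, and 72 sample columns, of which 69 hold values. Groups were taken from the labels alone. Recovered reads summed to 3420406 to 8003170 a library; a gene at the minimum value of 10 rests on few reads, and its counting error is large. No pair of replicates agreed within sampling noise, so none was counted as a single sample. Genes with a value of at least 10 in at least 6 libraries were tested, 13053 in all. limma 3.58.1 in R 4.3.3 fitted log2(value + 1) with the 12 groups in a single model and a mean-variance trend, so that all groups share an estimate of the spread, and p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The 11 treatments were each compared with DMSO, and 4 pairs of treatments directly. The 37 gene lists were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, adjusted over the lists, and again with an estimated correlation. The comparisons, lists, tests and most alternatives were fixed before the data were examined.

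Genes are named by a rule fixed then too: per comparison, the 10 largest rises and 10 largest falls among genes with a symbol, a mean value of at least 50, an adjusted p under 0.05 and libraries that do not overlap between the groups (all calls where these are few); up to 4 members of each list that passed camera or had at least 3 called members; the drugs' target genes; and a fixed panel of stress and metabolic genes. Results of some genes under this rule are not reported here.

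The alternatives fixed beforehand were a pseudocount of 10, no filter on low values, quantile normalization, the replicate number as a block, a fit of only the 2 groups compared, array weights, leaving out each replicate number from every group, an estimated correlation in camera, and split DMSO libraries. Added after the data were seen were setting aside 6 libraries, a correction for GC content (a loess curve per library, span 0.4, degree 1, on genes with a mean of at least 50, with degree 2 as a second setting, over the 12249 tested genes, 93.8%, with a GC value), edgeR 4.0.16 quasi-likelihood tests on the recovered whole reads, and leaving out DMSO replicates 1 and 2. By edgeR the genes called against DMSO were 424 (UK-5099), 256 (doxycycline), 34 (chloramphenicol), 559 (DNP), 106 (rotenone), 1038 (antimycin A), 711 (metformin), 1054 (etomoxir), 448 (FK866), 2546 (tunicamycin) and 64 (BPTES). A GC correction also removes real changes that follow GC content.

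The limma and edgeR steps were tested on simulated negative binomial counts with 200 genes changed, all with a mean of at least 50. Recovery of genes with lower means was not simulated. For antimycin A against DMSO, over 13053 genes, limma recovered 26.3% of genes changed by a log2 of 0.5, 79.2% at 1 and 100% at 2, with 9 false calls. For BPTES, with 3 libraries, it recovered 15.8%, 71.1% and 100% at the same sizes, with 5 false calls. A GC trend added to the antimycin A simulation, equal in all treated libraries, gave 79 false calls over 12249 genes, and 9 after correction. Recovery of the changed genes was 79.6% before the correction and 72.3% after it. The GC trends of the real libraries varied within groups, so the 79 does not measure the effect in the data. Similarity of treatments used 100 simulations of unchanged groups against the same controls and 10 splits of the controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.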

Results

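Gene expression was measured by RNA sequencing in primary human dermal fibroblasts, cells of normal skin obtained from ATCC, after 6 h with DMSO or with an inhibitor, in a series designed to study the response to mitochondrial stress. The 72 samples fall into 12 groups with 6 replicates each by their labels: DMSO (0.5%) and 11 treatments. UK-5099 (20 µM) blocks the mitochondrial pyruvate carrier, doxycycline (20 µg/mL) and chloramphenicol (100 µg/mL) the mitochondrial ribosome, and DNP (100 µM) uncouples respiration. Rotenone (100 nM) and metformin (2 mM) inhibit complex I of the respiratory chain and antimycin A (100 nM) complex III. Etomoxir (10 µM) inhibits carnitine palmitoyltransferase, FK866 (500 nM) the NAD-synthesis enzyme NAMPT, tunicamycin (1 µg/mL) N-linked glycosylation and BPTES (1 µM) the breakdown of glutamine. Metformin was diluted from a 50x stock and the other drugs from 200x stocks in DMSO, so the vehicle of the metformin samples may not match that of the controls. The table heads 72 columns, of which 69 hold values; BPTES replicates 4, 5 and 6 are empty, and BPTES has n = 3.

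Values were normalised counts for 17714 genes, and 13053 genes were tested. The whole reads recovered from the values summed to between 3420406 and 8003170 per library, with a median of 4451337; DMSO replicates 1 and 2 lay highest, and without them the highest total was 5980458. Changes are log2 changes ± standard error on the log2(value + 1) scale, which understates changes of low genes, and levels are means ± SD of normalised counts. A gene rose or fell where its adjusted p from limma, Benjamini-Hochberg corrected over the 13053 genes, was under 0.05. For the genes named for the largest rises and falls, all libraries of a group lay on the same side of all libraries of the other. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

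In 6 libraries the values of marker genes stood apart from the other libraries with the same label: replicate 6 of antimycin A, metformin, etomoxir and FK866, and replicates 5 and 6 of tunicamycin. HSPA5, the endoplasmic reticulum (ER) chaperone BiP, was at 64071 normalised counts in FK866 replicate 6 against 5014 to 5351 in the other 5 FK866 libraries, and at 3987 and 4178 in tunicamycin replicates 5 and 6 against 65254, 68129, 67219.8 and 63469 in replicates 1 to 4. Over the 300 genes that best separated the groups among the other 63 libraries, all 6 lay nearest to the group whose label follows in the table. Of the other 63 libraries 62 lay nearest to their own group, which the choice of genes on these same libraries favours. Rotenone replicate 6 lay nearest to its next label too, antimycin A, and was kept in. The values below use all 69 libraries as labelled; each count is followed by the count with these 6 libraries set aside, an alternative added after the data were seen. For groups that hold none of the 6, setting them aside left the folds as they were and lowered the spread shared by all groups.

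**Figure D1:**
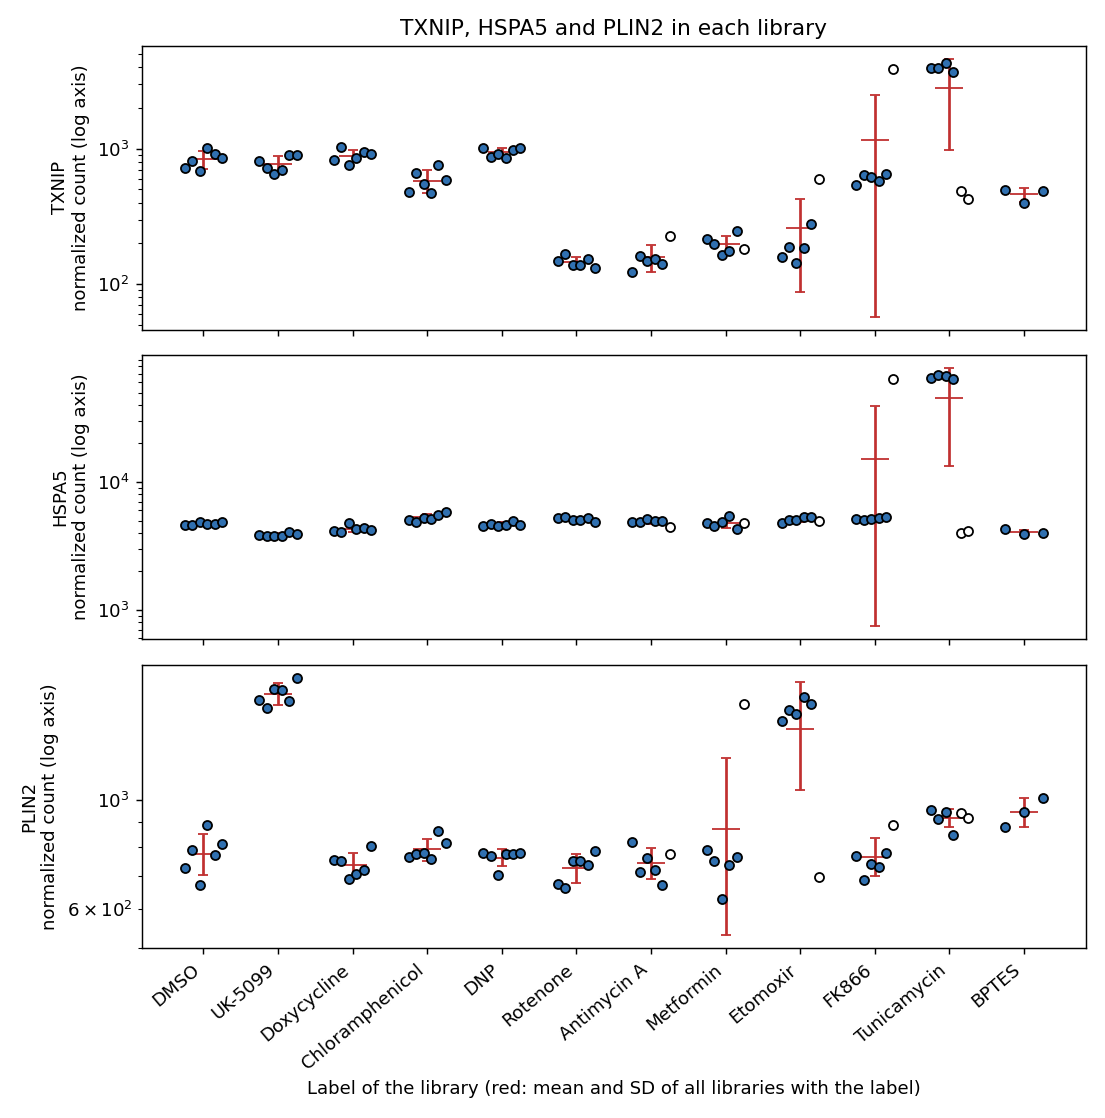
Normalised counts (log axis) of TXNIP, HSPA5 and PLIN2 in each of the 69 libraries by label, with the mean and SD of all libraries with that label in red. Open circles mark the 6 libraries set aside in an alternative, and the FK866 open circle reaches 64071 for HSPA5.

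Libraries also differed in how their values followed the GC content of genes. The slope of a library's log2 values, less the mean of all libraries, on GC fraction averaged -1.05 ± 0.56 (SD, n = 6) in DMSO, -1.66 ± 0.83 in UK-5099 and -1.17 ± 0.47 in tunicamycin, against 1.32 ± 0.47 in antimycin A, 1.25 ± 0.57 in etomoxir, 0.96 ± 0.78 in metformin and 0.24 ± 1.34 in FK866 (n = 6 each), the last at 0.71 ± 0.77 without replicate 6. The first 2 principal components held 7.02% and 5.59% of the variance, and their correlations with this slope over the 69 libraries were 0.626 and -0.746, as a description with no test. The labels name no batch. Beside each count stands the percentage of its calls with a GC value that were called in the same direction after a correction of each library for GC content, also added after the data were seen.

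**Figure D2:**
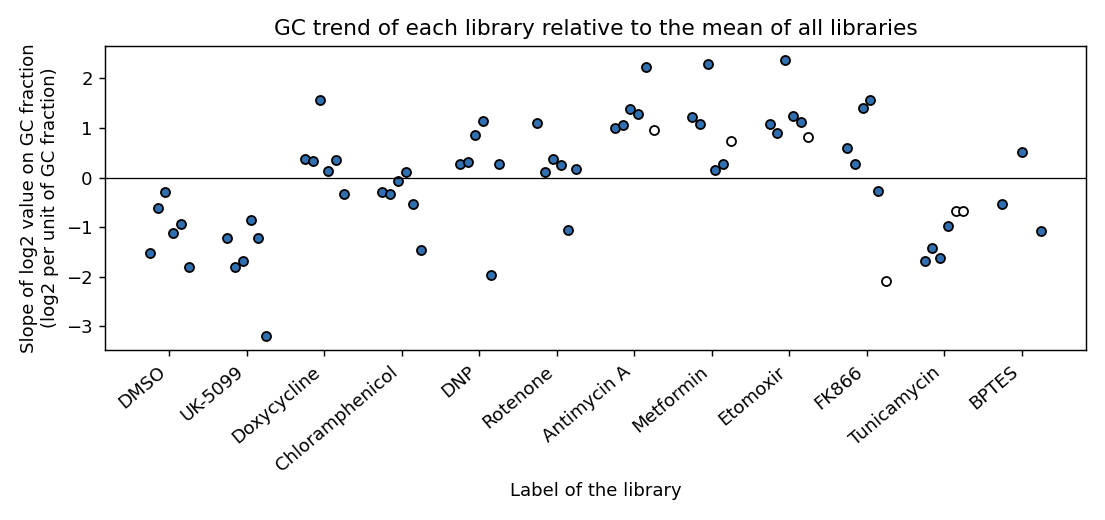
Slope of each library's log2 values on the GC fraction of genes, relative to the mean of all libraries, by label. Open circles mark the 6 libraries set aside in an alternative. DMSO libraries averaged -1.05 and antimycin A libraries 1.32.

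**Figure D3:**
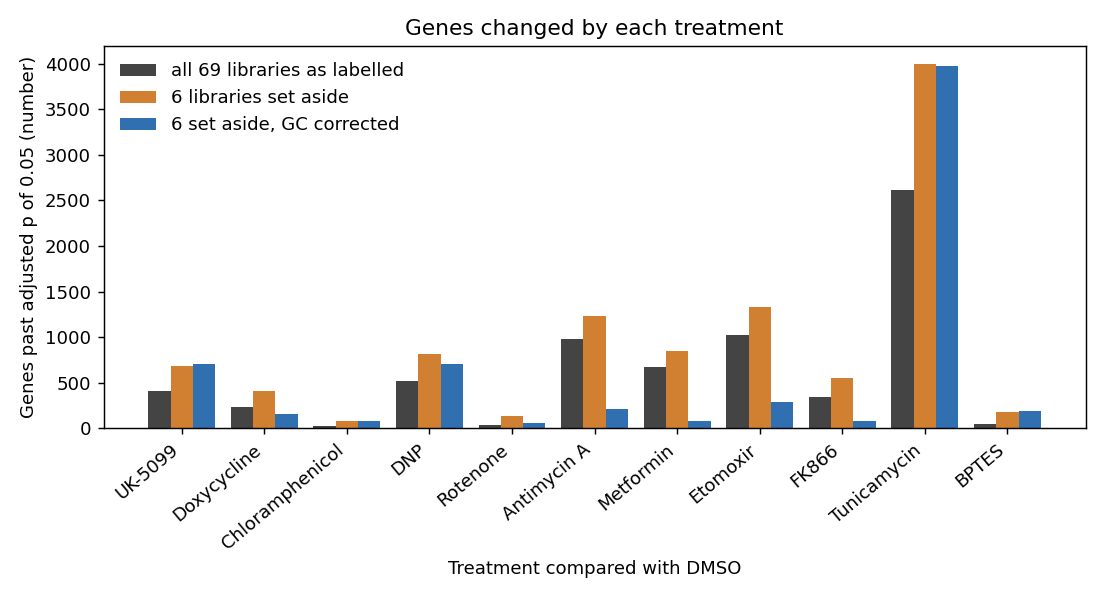
Number of genes with an adjusted p under 0.05 in each comparison (bars from 0), with all 69 libraries as labelled, with 6 libraries set aside, and with 6 set aside after GC correction. Antimycin A against DMSO gave 981, 1231 and 215 genes, and UK-5099 gave 405, 683 and 709.

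UK-5099 was compared with DMSO to see the response to a block of mitochondrial pyruvate uptake. The largest rise was in B3GNT2, a glycosyltransferase that extends poly-N-acetyllactosamine chains, at 306 ± 20.0 (SD, n = 6) against 127 ± 11.4 (n = 6), a log2 change of 1.26 ± 0.18. FST, the activin antagonist follistatin, rose by 1.12 ± 0.12, and HMOX1, which degrades heme, by 1.04 ± 0.09. Among fatty acid oxidation and lipid storage genes, 5 of 18 (5 adjusted over the list alone) rose and none fell, among them PLIN2, which coats lipid droplets, by 1.08 ± 0.12, ANGPTL4, an inhibitor of lipoprotein lipase, by 0.78 ± 0.23, CPT1A, which transfers long-chain acyl groups to carnitine at the outer mitochondrial membrane, by 0.52 ± 0.13, and ACAA2, the thiolase of beta-oxidation, by 0.49 ± 0.09. By camera the list gave adjusted p = 0.0216, and adjusted p = 0.1 with an estimated correlation. PLAU (ENSG00000122861, chromosome 10, 73909177 to 73917497), the urokinase-type plasminogen activator, fell from 90.0 ± 14.3 to 26.6 ± 6.87 (n = 6 each), a log2 change of -1.75 ± 0.17.

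GPRC5A, a retinoic acid-induced receptor, changed by -1.37 ± 0.25, and G0S2, an inhibitor of adipose triglyceride lipase, with -1.21 ± 0.24. With UK-5099, collagen and matrix genes fell in 3 of 23 (9 adjusted over the list alone), including COL1A1, a chain of type I collagen, by a log2 change of -0.94 ± 0.18. For that list camera gave adjusted p = 7.59e-07, and adjusted p = 0.00338 with an estimated correlation. Contractile and YAP/TGF-beta target genes fell in 3 of 15 (4 adjusted over the list alone), THBS1 (thrombospondin-1) with -0.62 ± 0.14. As a set they gave a camera adjusted p = 2.67e-04, and adjusted p = 0.0191 with an estimated correlation. Of the inflammatory cytokines and NF-kB targets 3 of 13 (3 adjusted over the list alone) fell, including BIRC3, an inhibitor of apoptosis, at -1.19 ± 0.26, and the chemokines CXCL8 at -1.11 ± 0.21 and CXCL1 at -0.97 ± 0.27. The set test (camera) gave adjusted p = 0.0216, and adjusted p = 0.174 with an estimated correlation. The metal-binding metallothioneins fell in 2 of 5 (3 adjusted over the list alone), MT2A with -0.75 ± 0.12 (camera adjusted p = 4.94e-04, and adjusted p = 0.0704 with an estimated correlation), and NRF2 targets rose in 3 of 18 (3 adjusted over the list alone). Over the list, camera gave adjusted p = 0.0216, and adjusted p = 0.0704 with an estimated correlation. HMGCS1, of cholesterol synthesis, changed by -0.67 ± 0.11. The pyruvate carrier subunits were at -0.02 ± 0.10, adjusted p = 0.948 (MPC1) and 0.02 ± 0.13, adjusted p = 0.97 (MPC2). In all, 405 genes changed with UK-5099, 191 up and 214 down (228 and 162 with quantile normalization), and 683 with the 6 libraries set aside; 92.1% were called the same way after GC correction. The count was 216 without replicate number 2.

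Doxycycline and chloramphenicol bind the mitochondrial ribosome, and the mRNAs that this ribosome translates are those of the mitochondrial genome. With doxycycline, 8 of 13 (9 adjusted over the list alone) of these mRNAs fell (camera adjusted p = 2.83e-15, and adjusted p = 0.0623 with an estimated correlation), and 1 rose when adjusted over the list alone. MT-ND4, a complex I subunit, fell with a log2 change of -0.56 ± 0.11, MT-ND4L with -0.41 ± 0.07, MT-ND5 with -0.39 ± 0.09 and MT-CYB, cytochrome b of complex III, with -0.36 ± 0.06. Mitochondrial mRNAs made up 3.46% ± 0.245 of normalised counts with doxycycline (SD, n = 6), 4.68% ± 0.201 with chloramphenicol (n = 6) and 4.25% ± 0.368 in DMSO (n = 6). After GC correction 5 of the list fell and 1 rose, with MT-ND5 at an adjusted p of 0.0736.

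Doxycycline raised ZNF282, a zinc finger protein, by a log2 change of 1.66 ± 0.40 and TNFRSF6B, a soluble decoy receptor for Fas ligand, by 1.19 ± 0.21, and lowered ANKRD1, a YAP target, with -0.64 ± 0.14; after GC correction the adjusted p of ZNF282 was 0.13 and that of ANKRD1 0.0627. No member of the list of stress response regulators was called by limma against DMSO, and 0 adjusted over the list alone (camera adjusted p = 1.27e-04, and adjusted p = 0.581 with an estimated correlation); with the 6 libraries set aside 8 of 19 rose, among them CHAC1, a glutathione-degrading enzyme, by 1.56 ± 0.29, and ATF4, the transcription factor of the integrated stress response, by 0.88 ± 0.23. Doxycycline changed 233 genes, 179 up and 54 down, and 412 with the 6 set aside; 12.9% of the calls were called the same way after GC correction, which left 44 genes called. The count fell to 77, 121, 73, 95 and 146 without replicate numbers 1, 2, 3, 4 and 5 in turn, and was 134 when only doxycycline and DMSO entered the fit. With the 6 set aside and GC corrected it was 158, against 412 with the 6 set aside alone.

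With chloramphenicol, 6 of 13 mitochondrial mRNAs rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 2.29e-21, and adjusted p = 0.0096 with an estimated correlation). MT-ND2 (ENSG00000198763, chromosome M, 4470 to 5511), a subunit of complex I, rose to 20927 ± 913 (SD, n = 6) against 9132 ± 870.2 (n = 6), a log2 change of 1.2 ± 0.07, MT-CYB rose by 0.45 ± 0.06 and MT-ND3 by 0.39 ± 0.05. MT-CO1, the catalytic subunit of cytochrome oxidase, fell with a log2 change of -0.43 ± 0.04. Outside the mitochondrial genome, ODC1, the ornithine decarboxylase of polyamine synthesis, rose by 0.38 ± 0.06 and CDKN1A, the cell cycle inhibitor p21, by 0.35 ± 0.07 (adjusted p = 0.0728 after GC correction), the member of the p53 targets called among 18 (1 adjusted over the list alone; camera adjusted p = 0.00295, and adjusted p = 0.0103 with an estimated correlation). Several of the called genes are nuclear copies of mitochondrial sequence, such as MTND2P28 and MTATP6P1, whose reads are uncertain because they match mitochondrial mRNAs. Chloramphenicol changed 28 genes, 16 up and 12 down, and 83 with the 6 libraries set aside; 81.5% were called the same way after GC correction.

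**Figure D4:**
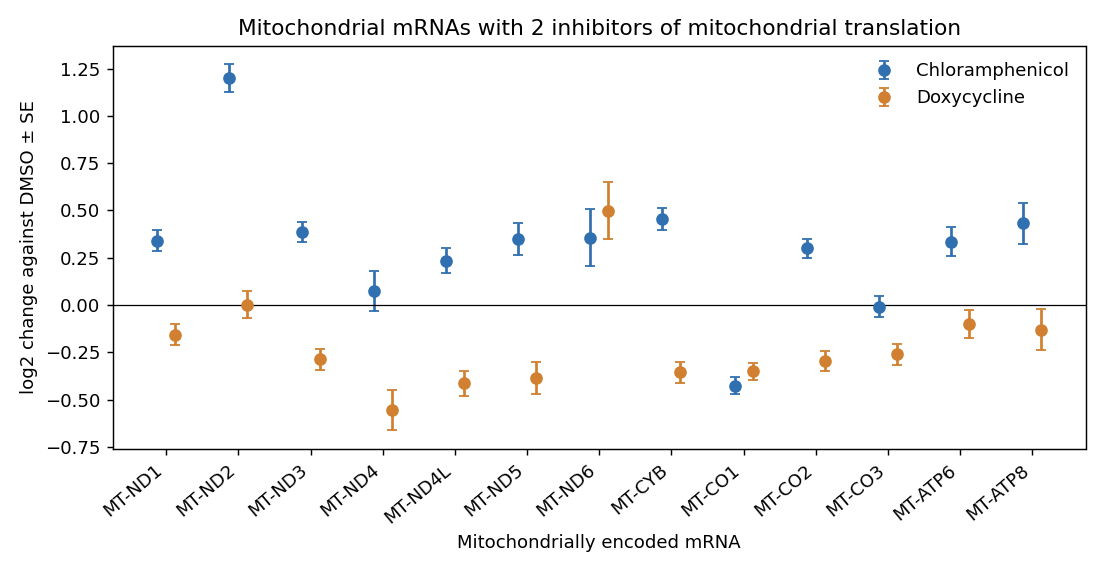
Log2 changes against DMSO (points, with standard errors, n = 6 against 6) of the 13 mitochondrially encoded mRNAs, chloramphenicol beside doxycycline. MT-ND2 was at 1.2 with chloramphenicol, and MT-ND4 at -0.56 with doxycycline.

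DNP was compared with DMSO to see the response to uncoupling. CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956519) rose to 159 ± 22 (SD, n = 6) against 7.39 ± 3.56 (n = 6), a log2 change of 4.33 ± 0.73. ADM2, the peptide adrenomedullin-2, rose by 4.14 ± 0.84, TRIB3, a pseudokinase induced by stress, by 2.15 ± 0.53 and ATF4 by 1.79 ± 0.34; of the stress response regulators 12 of 19 (12 adjusted over the list alone) rose. By camera the list gave adjusted p = 1.78e-18, and adjusted p = 0.0172 with an estimated correlation. Amino acid and one-carbon synthesis genes rose in 8 of 17 (10 adjusted over the list alone), PSAT1, of serine synthesis, by 2.35 ± 0.43 and ASNS, asparagine synthetase, by 1.84 ± 0.46. For that list camera gave adjusted p = 4.24e-11, and adjusted p = 0.0658 with an estimated correlation. Amino acid transporters rose in 5 of 11 (8 adjusted over the list alone), SLC7A11, the cystine transporter, by 2.14 ± 0.31, SLC7A5, for large neutral amino acids, by 2.07 ± 0.34 and SLC6A9, for glycine, by 2.44 ± 0.65. As a set they gave a camera adjusted p = 2.89e-09, and adjusted p = 0.0258 with an estimated correlation. NRF2 targets, of the antioxidant response, rose in 8 of 18 (12 adjusted over the list alone) (camera adjusted p = 1.03e-11, and adjusted p = 8.31e-08 with an estimated correlation), HMOX1 by 0.80 ± 0.09.

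Contractile and YAP/TGF-beta targets rose with DNP in 5 of 15 (6 adjusted over the list alone) (camera adjusted p = 2.97e-07, and adjusted p = 0.00105 with an estimated correlation), and inflammatory cytokines and NF-kB targets in 5 of 13 (6 adjusted over the list alone). The set test (camera) gave adjusted p = 2.97e-07, and adjusted p = 0.00431 with an estimated correlation. CAVIN2, a coat protein of caveolae, fell with a log2 change of -1.45 ± 0.18 and PLAU with -1.05 ± 0.17. UCP2, a mitochondrial carrier of the uncoupling protein family, was at 0.52 ± 0.41, adjusted p = 0.582. In all 520 genes changed with DNP, 335 up and 185 down, and 817 with the 6 libraries set aside; 59.9% were called the same way after GC correction. The count was 277, 270, 313, 213 and 335 without replicate numbers 1, 2, 3, 4 and 6 in turn.

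Rotenone, antimycin A and metformin were compared with DMSO as inhibitors of the respiratory chain. With rotenone, TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600), an arrestin-like protein that restrains glucose uptake, fell to 146 ± 13.2 (SD, n = 6) against 834 ± 124 (n = 6), a log2 change of -2.50 ± 0.36. ARRDC4, a related arrestin domain protein, fell with a log2 change of -2.13 ± 0.29. Both are targets of the glucose-sensing transcription factor MondoA, and 2 of 3 (2 adjusted over the list alone) on that list fell. Over the list, camera gave adjusted p = 1.71e-08, and adjusted p = 1.3e-04 with an estimated correlation. Of the p53 targets 2 of 18 (2 adjusted over the list alone) rose, FDXR, a mitochondrial ferredoxin reductase, by 0.71 ± 0.17 and CDKN1A by 0.35 ± 0.07 (camera adjusted p = 6.22e-04, and adjusted p = 0.00345 with an estimated correlation); 0 were called after GC correction, where the adjusted p of FDXR was 0.332 and that of CDKN1A 0.235. PNPLA2, adipose triglyceride lipase, rose by 0.82 ± 0.16, and its adjusted p was 0.113 after GC correction. Rotenone changed 37 genes, 27 up and 10 down, and 133 with the 6 libraries set aside; 11.4% of the calls were called the same way after GC correction. The count was 4, 6, 24, 5, 164 and 7 without replicate numbers 1, 2, 3, 4, 5 and 6 in turn, 11 when only rotenone and DMSO entered the fit, and 106 by edgeR on the recovered reads. With the 6 set aside and GC corrected it was 53, against 133 with the 6 set aside alone.

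Antimycin A lowered TXNIP to 159 ± 35.7 (SD, n = 6) against 834 ± 124 (n = 6), a log2 change of -2.39 ± 0.36, and ARRDC4 with -2.06 ± 0.29; ARRDC3 also fell, with -0.59 ± 0.19, so that 3 of 3 (3 adjusted over the list alone) MondoA targets fell. By camera the list gave adjusted p = 5.58e-06, and adjusted p = 0.00225 with an estimated correlation. Of 17 immediate early genes, 2 rose and 1 fell (4 and 1 adjusted over the list alone): KLF2, a Krüppel-like factor, rose by 1.82 ± 0.47, JUNB, an AP-1 subunit, by 1.13 ± 0.34, and the nuclear receptor NR4A2 changed by -1.93 ± 0.43. Mitosis genes fell in 2 of 24 (3 adjusted over the list alone). For that list camera gave adjusted p = 0.00172, and adjusted p = 0.406 with an estimated correlation. GC-rich genes were prominent among the rises: METRN, the secreted factor meteorin, rose by 1.93 ± 0.30 at a GC content of 69.3%, and JOSD2, a deubiquitinase, by 1.52 ± 0.22 at 68.4%; after GC correction their adjusted p was 0.00336 and 0.00542. KIF18A, a mitotic kinesin, fell with a log2 change of -0.75 ± 0.14. UQCRC1 and UQCRFS1, subunits of complex III, were at -0.10 ± 0.06, adjusted p = 0.386 and 0.05 ± 0.05, adjusted p = 0.66.

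With antimycin A, 981 genes changed, 733 up and 248 down, and 1231 with the 6 libraries set aside. Of the calls, 12.5% were called the same way after GC correction, with the median absolute change of the called genes moving from 0.55 to 0.24 and their median standard error from 0.14 to 0.12. TXNIP (adjusted p = 3.13e-05) and ARRDC4 (adjusted p = 5.98e-06) were called after that correction, while ARRDC3, KLF2 and JUNB were not (adjusted p = 0.351, 0.267 and 0.44). The number of antimycin A calls was 583 without replicate number 1.

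With metformin, TXNIP fell to 197 ± 29.5 (SD, n = 6) against 834 ± 124 (n = 6), a log2 change of -2.08 ± 0.36, and ARRDC4 fell with a log2 change of -1.55 ± 0.29; 2 of 3 (2 adjusted over the list alone) MondoA targets fell. As a set they gave a camera adjusted p = 2.2e-04, and adjusted p = 0.0161 with an estimated correlation. Collagen and matrix genes rose in 4 of 23 (4 adjusted over the list alone), COL6A2, a chain of type VI collagen, by 0.87 ± 0.14 and COL1A1 by 0.59 ± 0.18 (camera adjusted p = 0.00327, and adjusted p = 0.18 with an estimated correlation); 2 were called as higher after GC correction, where COL1A1 had an adjusted p of 0.438. The largest rises were in IRF1, interferon regulatory factor 1, by 2.91 ± 0.72 and ULK1, the kinase that starts autophagy, by 1.90 ± 0.49, with adjusted p of 0.0618 and 0.2 after GC correction, and PNPLA2 rose by 1.14 ± 0.16 (adjusted p = 0.00343 after it). Cytosolic ribosomal protein genes went both ways, 9 up and 14 down of 82 (11 and 31 adjusted over the list alone; camera adjusted p = 3.85e-04, and adjusted p = 0.592 with an estimated correlation). In all, 675 genes changed with metformin, 498 up and 177 down, and 846 with the 6 libraries set aside; 4.63% of the calls were called the same way after GC correction. The count was 211, 339, 319 and 390 without replicate numbers 1, 2, 3 and 6 in turn, and 272 when only metformin and DMSO entered the fit.

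Etomoxir was compared with DMSO to see the response to a block of fatty acid import. Fatty acid oxidation and lipid storage genes rose in 4 of 18 (7 adjusted over the list alone), and 1 fell (camera adjusted p = 0.186, and adjusted p = 0.543 with an estimated correlation), with ANGPTL4 at 1.02 ± 0.23 and PLIN2 at 0.79 ± 0.12; PLIN2 was at 1392 ± 347 (SD, n = 6) against 777 ± 74.8 (n = 6). TXNIP fell with a log2 change of -1.87 ± 0.36 and ARRDC4 with -1.57 ± 0.29, in 2 of 3 (3 adjusted over the list alone) MondoA targets. The set test (camera) gave adjusted p = 6.31e-04, and adjusted p = 0.0431 with an estimated correlation. Without replicate 6 the etomoxir means were 1532 ± 66.6 for PLIN2 (SD, n = 5), 191 ± 52.6 for TXNIP and 56.6 ± 12.9 for ARRDC4. In DMSO, TXNIP was at 834 ± 124 and ARRDC4 at 201 ± 11.5 (SD, n = 6). Mitosis genes fell in 3 of 24 (8 adjusted over the list alone). Over the list, camera gave adjusted p = 2.92e-05, and adjusted p = 0.146 with an estimated correlation. METRN rose by 1.85 ± 0.30 and LTBP4, which binds latent TGF-beta, by 1.4 ± 0.34, with adjusted p of 0.0068 and 0.194 after GC correction. HMGCS1 changed by -0.41 ± 0.11 (after GC correction its adjusted p was 0.259 and that of ANGPTL4 0.169), and CPT1A, the drug's target, was at 0.33 ± 0.13, adjusted p = 0.104, and at 0.40 ± 0.14, adjusted p = 0.049, with the 6 libraries set aside. The largest fall was in SCHIP1, at -6.94 ± 1.79 with 6.16 ± 8.68 (SD, n = 6) against 547 ± 339.8 (n = 6), which is uncertain because SCHIP1 overlaps a readthrough gene that shares its exons. In all, 1023 genes changed with etomoxir, 730 up and 293 down, and 1330 with the 6 libraries set aside; 13.6% of the calls were called the same way after GC correction. The count was 586 without replicate number 1.

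With FK866, which blocks the salvage of nicotinamide to NAD, mitosis genes fell in 3 of 24 (4 adjusted over the list alone) (camera adjusted p = 2.53e-05, and adjusted p = 0.098 with an estimated correlation). This includes replicate 6, which lay nearest to tunicamycin, where mitosis genes fell too, so the fall may not be an effect of FK866. Among the stress response regulators 1 of 19 (1 adjusted over the list alone) rose, PPP1R15A, a regulator of eIF2-alpha dephosphorylation, by 0.71 ± 0.18 (camera adjusted p = 2.27e-05, and adjusted p = 0.354 with an estimated correlation). No member of the ER folding and degradation list was called by limma, and 0 adjusted over the list alone, though camera's preset correlation passed it (camera adjusted p = 7.39e-05, and adjusted p = 0.507 with an estimated correlation; camera adjusted p = 0.238 with the 6 libraries set aside). In FK866 replicate 6 the stress genes stood far above the other libraries of that label, CHAC1 at 541, and the list test as labelled includes that library. Without it the FK866 means were 677 for ATF4 (607 in DMSO), 46.5 for DDIT3 (47.5) and 38.4 for TRIB3 (23.2). CHAC1 was then at 12.3 (7.39 in DMSO) and GDF15 at 3.58 (2.67). PNPLA2 rose by 1.07 ± 0.16, with an adjusted p of 0.00172 after GC correction, and RAVER1, an RNA-binding protein, by 1.21 ± 0.27, with 0.0721. HSP90AA1, a cytosolic chaperone, fell with a log2 change of -0.27 ± 0.06, with 0.178 after GC correction against 0.104 for PPP1R15A, and NAMPT, the target, was at 0.23 ± 0.17, adjusted p = 0.562. Without replicate 6 the NAMPT mean was 565 ± 84.2 (SD, n = 5) against 537 ± 98.8 in DMSO (n = 6). In all, 347 genes changed with FK866, 264 up and 83 down, and 548 with the 6 libraries set aside; 21.4% of the calls were called the same way after GC correction. The count was 119, 228 and 168 without replicate numbers 1, 3 and 4 in turn, and 27 when only FK866 and DMSO entered the fit.

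Tunicamycin, which blocks N-linked glycosylation and so loads the ER with unfolded proteins, was the reference for ER stress. All 24 ER folding and degradation genes rose, 24 adjusted over the list alone (camera adjusted p = 1.28e-22, and adjusted p = 0.0383 with an estimated correlation). HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330) rose to 45373 ± 32024 (SD, n = 6) against 4712 ± 113 (n = 6), a log2 change of 2.47 ± 0.42, and by 3.81 ± 0.04 with replicates 5 and 6 set aside; DNAJB9, an ER co-chaperone, rose by 3.08 ± 0.54 and HERPUD1, of ER-associated degradation, by 2.96 ± 0.54 (4.64 ± 0.19 and 4.61 ± 0.15 with these set aside). Stress response regulators rose in 16 of 19 (18 adjusted over the list alone), with ADM2 at 4.65 ± 0.84, TRIB3 at 4.06 ± 0.53, CHAC1 at 3.98 ± 0.73, DDIT3, the transcription factor CHOP, at 3.74 ± 0.62 and GDF15, a secreted stress cytokine, at 3.40 ± 0.60 (camera adjusted p = 1.7e-19, and adjusted p = 0.0239 with an estimated correlation). With replicates 5 and 6 set aside these were at 7.07 ± 0.38 (ADM2), 5.59 ± 0.17 (TRIB3), 6.17 ± 0.33 (CHAC1), 5.60 ± 0.14 (DDIT3) and 4.90 ± 0.42 (GDF15). Amino acid and one-carbon synthesis genes rose in 16 of 17 (16 adjusted over the list alone) (camera adjusted p = 3.14e-13, and adjusted p = 0.0269 with an estimated correlation), amino acid transporters in 8 of 11 (9 adjusted over the list alone) (camera adjusted p = 1e-08, and adjusted p = 0.024 with an estimated correlation) and cytosolic aminoacyl-tRNA synthetases in 11 of 15 (13 adjusted over the list alone) (camera adjusted p = 5.69e-07, and adjusted p = 0.0853 with an estimated correlation).

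DNA replication genes fell with tunicamycin in 17 of 23 (18 adjusted over the list alone), and CDC6, which loads the replicative helicase, rose (camera adjusted p = 1.73e-11, and adjusted p = 0.0239 with an estimated correlation). Mitosis genes fell in 14 of 24 (14 adjusted over the list alone) (camera adjusted p = 5.69e-07, and adjusted p = 0.024 with an estimated correlation) and genes of glycolysis and glucose uptake in 10 of 21 (12 adjusted over the list alone) (camera adjusted p = 1.74e-05, and adjusted p = 0.024 with an estimated correlation). HAS2, hyaluronan synthase, fell with a log2 change of -2.13 ± 0.28, PODXL, podocalyxin, with -2.26 ± 0.31 and HSPA8, the constitutive HSP70, with -1.25 ± 0.18. TXNIP rose by 1.22 ± 0.36 and NAMPT by 0.72 ± 0.17; with replicates 5 and 6 set aside HAS2 was at -2.91 ± 0.10, PODXL at -3.17 ± 0.11, TXNIP at 2.26 ± 0.13 and NAMPT at 1.12 ± 0.13. DPAGT1, the target of tunicamycin, was at 0.39 ± 0.16, adjusted p = 0.0884, and at 0.64 ± 0.15, adjusted p = 5.97e-04, with these set aside. Tunicamycin changed 2609 genes, 1273 up and 1336 down, and 3993 with the 6 libraries set aside; 92.1% were called the same way after GC correction. The count was 1651, 1608 and 1703 without replicate numbers 1, 2 and 4 in turn, and 919 when only tunicamycin and DMSO entered the fit.

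BPTES was compared with DMSO to see the response to a block of glutamine breakdown, with n = 3. KLHL24 (ENSG00000114796, chromosome 3, 183635568 to 183684477), a substrate adaptor for ubiquitin ligation, rose to 138 ± 51.7 (SD, n = 3) against 25.2 ± 8.7 (n = 6), a log2 change of 2.41 ± 0.53. SQSTM1, the autophagy receptor p62, rose by 0.88 ± 0.15 and FNIP1, a folliculin partner, by 0.61 ± 0.13; 2 of 23 (5 adjusted over the list alone) lysosome and FLCN-TFEB targets rose (camera adjusted p = 9.93e-06, and adjusted p = 1.17e-04 with an estimated correlation). PLAT, tissue plasminogen activator, fell with a log2 change of -0.55 ± 0.11 and FEZ2 with -0.54 ± 0.09. The mitochondrial mRNAs MT-ND1 and MT-ND2 rose by 0.27 ± 0.07 and 0.37 ± 0.09. BPTES changed 50 genes, 25 up and 25 down, and 179 with the 6 libraries set aside, none of which has this label or the DMSO label; 91.7% of the calls were called the same way after GC correction. The count was 7, 6, 31 and 16 without replicate numbers 1, 2, 3 and 4 in turn, of which numbers 4 to 6 remove no BPTES library, 59 without number 5, and 10 when only BPTES and DMSO entered the fit.

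Rotenone and antimycin A, inhibitors of complexes I and III at the same concentration, were compared directly. No gene differed by limma at an adjusted p under 0.05; 1082 genes had an unadjusted p under 0.05, and edgeR on the recovered reads called 4. TXNIP was at -0.10 ± 0.36, adjusted p = 0.975 and ARRDC4 at -0.06 ± 0.29, adjusted p = 0.983. Mitosis genes were higher with rotenone as a list, with a median log2 difference of 0.15 (camera adjusted p = 2.68e-05, and adjusted p = 0.285 with an estimated correlation); 0 members were called, 3 adjusted over the list alone. The count was 1 and 8 without replicate numbers 3 and 6 in turn, and 15 with the 6 libraries set aside. Rotenone replicate 6, which lay nearest to antimycin A, is in the rotenone group also in that count of 15. If it holds antimycin A, it would make differences between the groups smaller.

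Doxycycline and chloramphenicol act on the same ribosome and differed in their mitochondrial mRNAs: 11 of 13 (11 adjusted over the list alone) were lower with doxycycline (camera adjusted p = 1.37e-60, and adjusted p = 5.91e-07 with an estimated correlation). MT-ND2 differed by -1.2 ± 0.07 and MT-CYB with -0.81 ± 0.06. XPO1, the nuclear export receptor, wlower with doxycycline, at -0.88 ± 0.14, while S1PR3, a sphingosine-1-phosphate receptor, was higher by 0.47 ± 0.06 and AKAP12, a kinase anchoring protein, by 0.40 ± 0.07. In all 41 genes differed, 15 higher and 26 lower with doxycycline, and 106 with the 6 libraries set aside; 87.2% were called the same way after GC correction. The doses of the antibiotics differ, 20 and 100 µg/mL.

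Rotenone and metformin, both complex I inhibitors, differed in 1 gene by limma, the pseudogene SMG1P1, at 2.91 ± 0.55, whose reads are uncertain because near-identical copies exist; 818 genes had an unadjusted p under 0.05, and edgeR called 4. TXNIP was at -0.42 ± 0.36, adjusted p = 0.895. Of the mitosis genes 0 were called, 2 adjusted over the list alone, and camera gave adjusted p = 3e-06, or adjusted p = 0.153 with an estimated correlation. The count was 0, 0, 0 and 2 without replicate numbers 1, 3, 5 and 6 in turn, 11 with the 6 libraries set aside and 0 when only these groups entered the fit. A p that misses the threshold does not show that the drugs act alike.

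Antimycin A and tunicamycin were compared as mitochondrial against ER stress. Of the ER folding and degradation genes 23 of 24 (23 adjusted over the list alone) were lower with antimycin A (camera adjusted p = 2.59e-20, and adjusted p = 0.0707 with an estimated correlation), and TRIB3 differed by -3.78 ± 0.53. TXNIP differed by -3.61 ± 0.36, with 159 ± 35.7 (SD, n = 6) against 2791 ± 1819.5 (n = 6), and ARRDC4 with -3.24 ± 0.29. HAS2 was higher with antimycin A by 2.09 ± 0.28 and JUN, an AP-1 subunit, by 1.68 ± 0.23. With the 6 libraries set aside the differences were -5.30 ± 0.18 (TRIB3), -4.76 ± 0.13 (TXNIP), -4.09 ± 0.12 (ARRDC4), 2.88 ± 0.11 (HAS2) and 2.35 ± 0.08 (JUN). Genes of glycolysis and glucose uptake were higher in 13 of 21 (13 adjusted over the list alone) (camera adjusted p = 3.28e-07, and adjusted p = 0.0176 with an estimated correlation). In all 3143 genes differed, 1587 higher and 1556 lower with antimycin A; the count was 4139 with the 6 libraries set aside and 2087 when only these groups entered the fit. Of the calls 56.2% were called the same way after GC correction.

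Changes against DMSO were compared between treatments across 9179 genes, in 55 pairs that share the DMSO libraries; genes are not independent replicates. Antimycin A and etomoxir had the highest correlation, r = 0.784, against 0.497 for simulated unchanged groups with the same controls, and a covariance of 0.0934 against a simulated 0.0257. Metformin and etomoxir were at r = 0.779 (covariance 0.0835), and antimycin A and metformin at r = 0.75 (covariance 0.0797). With the controls split, so that the treatments shared no DMSO library, the same pairs were at 0.48, 0.448 and 0.422. With the controls split, the 6 libraries set aside and GC corrected they were at 0.258, 0.225 and 0.178, and DNP and tunicamycin were the highest pair at 0.285, against r = 0.524 as labelled. With GC correction alone metformin and etomoxir, at 0.663, lay above antimycin A and etomoxir, at 0.654. Antimycin A and etomoxir shared 548 rises and 114 falls, where independent lists would share 41 and 5.57, values that leave out the shared DMSO libraries. With each treatment tested against 3 DMSO libraries that the other was not, an alternative added after the data were seen, they shared a median of 209 rises (132 to 227 over 20 assignments) and 15.5 falls, where independent lists would share 11.5 and 0.644. These overlaps carry no GC correction. The changes of both treatments followed GC content, with r of 0.565 and 0.544 across genes. Splitting the controls does not remove this, since all DMSO slopes on GC fraction lay between -1.80 and -0.29.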

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

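The tests of labels, mixing and GC content were chosen only after the results were seen; the test of DMSO replicates 1 and 2 and the counts of other splits were written before, though the split counts with 6 libraries set aside use an alternative chosen after the data were seen. A library was listed where its gap to the nearest other library of its group, relative to the group's range, passed Dixon's critical value. This happened in 32 of 264 groups tested, 16 of them in the 6 libraries set aside above, and chance alone gives about 1 in 20.

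In FK866 replicate 6, normalised counts lay apart from the other 5 libraries for ATF4 at 2251 (511 to 855 in the others), DDIT3 at 2298 (35 to 56.6 in the others), ASNS at 1613 (87.7 to 155 in the others), TRIB3 at 1104 (31.3 to 46.2 in the others), CHAC1 at 541 (7.24 to 18 in the others), GDF15 at 82.2 (2.1 to 6.25 in the others), PSAT1 at 1488 (88.5 to 103 in the others), MTHFD2 at 1318 (177 to 229 in the others), HSPA5 at 64071 (5014 to 5351 in the others), TXNIP at 3883 (539 to 651 in the others), ARRDC4 at 789.7 (160.3 to 190.1 in the others) and NAMPT at 1041 (444 to 650.3 in the others). In the other libraries set aside, the same held for TXNIP in antimycin A replicate 6 at 227 (124 to 162 in the others) and in etomoxir replicate 6 at 593 (144 to 279 in the others). It also held for ARRDC4 in etomoxir replicate 6 at 171 (43.4 to 76.4 in the others) and HMOX1 in metformin replicate 6 at 295 (191 to 224 in the others).

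Among the remaining libraries, the listed values were the percentage of mitochondrial mRNA in chloramphenicol replicate 1 at 4.3 (4.68 to 4.86 in others), the GC slope in DNP replicate 5 at -1.96 (0.27 to 1.15 in others), recovered reads in antimycin A replicate 2 at 5305053 (4451337 to 4724382 in others), the GC slope in antimycin A replicate 5 at 2.22 (0.96 to 1.38 in others), the GC slope in etomoxir replicate 3 at 2.37 (0.82 to 1.23 in others), ARRDC4 in UK-5099 replicate 3 at 172 (149 to 154 in others), MPC1 in rotenone replicate 4 at 143 (111 to 122 in others) and MPC2 in UK-5099 replicate 2 at 236 (188 to 205 in others). Further ones were UCP2 in UK-5099 replicate 2 at 33.3 (6.77 to 15.2 in others), UCP2 in chloramphenicol replicate 3 at 46 (7.96 to 16.2 in others), UCP2 in DNP replicate 2 at 40.9 (4.99 to 18.3 in others), UCP2 in metformin replicate 1 at 51.6 (9.51 to 15.1 in others), UCP2 in tunicamycin replicate 3 at 15.2 (7.4 to 9.69 in others), UQCRC1 in doxycycline replicate 3 at 679 (828 to 841 in others), UQCRFS1 in doxycycline replicate 6 at 383 (421 to 440.1 in others) and DPAGT1 in rotenone replicate 4 at 289 (196 to 227 in others).

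The 6 libraries set aside lay nearest to the label that follows their own in the table: antimycin A replicate 6 to metformin, metformin 6 to etomoxir, etomoxir 6 to FK866, FK866 6 to tunicamycin, and tunicamycin 5 and 6 to BPTES. A wrong label was taken to predict that at least 5 of the 6 lie nearest to the next label, and 6 did. That prediction was written after the 6 had been picked for their values, so the count describes them and is not an independent test. On a line from the mean of the own label at 0 to that of the next at 1, they lay at 0.81 to 1. A mixture of RNA predicts places in between, and the median of 0.96 argues against it. A candidate explanation is a shift of column headings towards the 3 empty BPTES columns, which the labels cannot settle. Outside the 6, rotenone replicate 6 also lay nearest to its next label, antimycin A. It lay at 0.6 on that line, with a distance of 1.31 to antimycin A against 1.6 to rotenone. It stayed in the rotenone results, also where the 6 were set aside. A shift of headings could include this library, which its place on the line does not settle. If so, the rotenone results hold a library of antimycin A. No biological explanation was tested.

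Changes with antimycin A, metformin, etomoxir and FK866 against DMSO followed the GC content of genes, with r of 0.565, 0.533, 0.544 and 0.367 across genes, as did those with doxycycline and rotenone, with 0.402 and 0.367, where 12.9% and 11.4% of the calls were called the same way after GC correction. With the 6 libraries set aside r was 0.485 with FK866, 0.566 with antimycin A, 0.528 with metformin and 0.544 with etomoxir. DNP was at r = 0.313 (59.9% of calls kept) and antimycin A against tunicamycin at 0.437 (56.2%). The remaining treatments against DMSO lay between -0.178 (UK-5099) and 0.199 (chloramphenicol). If a difference between libraries that follows GC content were the cause, few calls would hold after the correction, and a median of 13% over the first 4 did. It was not the whole cause for TXNIP and ARRDC4, whose falls with rotenone, antimycin A, metformin and etomoxir were called in 8 of 8 cases after it. Median changes of the called genes fell more than their standard errors did, for antimycin A from 0.55 to 0.24 with a standard error from 0.14 to 0.12, so calls ended through smaller changes. Whether the GC trend came from library preparation or from the drugs stays open, since the labels name no batch.

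DMSO replicates 1 and 2 had the highest read totals and few genes with exactly 1 read, 179 and 171 against 840 or more in the other libraries. If their reads had been counted about 2 times, the noise between them would lie well above that of the other DMSO pairs at the same recovered depth. The ratio to the median of the 14 other pairs was 1.53 (4.39 against 2.87), between the bounds set beforehand, so this test does not decide. Those 14 include pairs of replicate 1 or 2 with another library, at 2.85 to 3.29. Counting about 2 times would raise the noise of these pairs as well and so lower the ratio, which made the test weak. Over the 6 pairs that hold neither library, a comparison the written test did not name, the median noise was 2.19. Among genes with 1 to 20 reads, 59.9% and 59.4% had even counts, against a median of 43.5% over all libraries. What produced these values stays open. Without these libraries 206 genes changed with UK-5099 and 62 with rotenone.

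Other splits of the samples were drawn, 100 a comparison with the real split included, out of up to 462 possible ones. Splits that were not drawn could hold as many genes. Nor can splits tell a drug effect from a preparation difference shared by a group. Only the real split gave as many genes in the comparisons named next, a share of 1 in 100 where 100 were drawn. These were UK-5099 with 405 genes (highest other 43), doxycycline with 233 (65), chloramphenicol with 28 (25) and DNP with 520 (25). Next came rotenone with 37 (2), antimycin A with 981 (300), metformin with 675 (393) and etomoxir with 1023 (217). The same held for FK866 with 347 (185), tunicamycin with 2609 (2276), doxycycline against chloramphenicol with 41 (19) and antimycin A against tunicamycin with 3143 (2567). Over all 84 splits, BPTES had 50 (5). Chance could not be excluded for rotenone against metformin, where 7 of 100 gave at least 1 (highest other 2). For rotenone against antimycin A the real count was 0, which 100 of 100 splits reach by construction (highest other 1), so the splits decide nothing there. With the 6 libraries set aside, 1 split gave as many in each: antimycin A with 1231 (125), metformin with 846 (522), etomoxir with 1330 (616), FK866 with 548 (118), tunicamycin with 3993 (1894), rotenone against antimycin A with 15 (10), rotenone against metformin with 11 (10) and antimycin A against tunicamycin with 4139 (3007).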

How the results depend on the processing

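Alternatives that set 6 libraries aside, corrected for GC content, used edgeR or left out DMSO replicates 1 and 2 were chosen after the data were seen, as were the values of r without each replicate number; the others were planned. Of the 660 calls on named genes, a pseudocount of 10 ended 7, the replicate block 13, array weights 6, quantile normalization 46, no filter 54, edgeR 29, setting aside 6 libraries 12, leaving out DMSO replicates 1 and 2 136 and a fit of only the 2 groups compared 250. GC correction ended 215 of 651 and turned the direction of 15. Leaving out a replicate number in turn ended 87 to 223 calls, with fewer libraries in the groups that hold that number; for the other changes the cause was not tested. Depth was 3420406 to 8003170 reads a library, which limits genes near the value minimum of 10. Same-numbered libraries deviated together with a mean r of 0.0019, against -4e-04 for other numbers, and 11 of 69 libraries correlated best with their own number, so the numbers were not taken to pair the samples.

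As labelled, the number of genes changed was 405 (UK-5099), 233 (doxycycline), 28 (chloramphenicol), 520 (DNP), 37 (rotenone), 981 (antimycin A), 675 (metformin), 1023 (etomoxir), 347 (FK866), 2609 (tunicamycin), 50 (BPTES), 0 (rotenone against antimycin A), 41 (doxycycline against chloramphenicol), 1 (rotenone against metformin) and 3143 (antimycin A against tunicamycin). The number of gene lists past the threshold was 12 (UK-5099), 7 (doxycycline), 6 (chloramphenicol), 15 (DNP), 6 (rotenone), 2 (antimycin A), 6 (metformin), 7 (etomoxir), 13 (FK866), 17 (tunicamycin) and 13 (BPTES). Similarity r was 0.784 (antimycin A and etomoxir), 0.779 (metformin and etomoxir) and 0.75 (antimycin A and metformin).

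With a pseudocount of 10, the number of genes changed was 0 (rotenone against metformin). With a pseudocount of 10, r was 0.799 (antimycin A and etomoxir). With no filter on low values, the number of genes changed was 20 (rotenone). With no filter on low values, the number of gene lists past the threshold was 6 (antimycin A). With no filter on low values, r was 0.679 (antimycin A and etomoxir), 0.65 (metformin and etomoxir) and 0.641 (antimycin A and metformin). With quantile normalization, the number of gene lists past the threshold was 3 (metformin) and 4 (etomoxir). With the replicate number as a block, the number of genes changed was 111 (rotenone) and 1 (rotenone against antimycin A). With only the 2 groups compared in the fit, the number of genes changed was 134 (doxycycline), 11 (rotenone), 272 (metformin), 27 (FK866), 919 (tunicamycin), 10 (BPTES), 0 (rotenone against metformin) and 2087 (antimycin A against tunicamycin). With only the 2 groups compared in the fit, the number of gene lists past the threshold was 14 (doxycycline) and 10 (metformin). With array weights, the number of genes changed was 624 (UK-5099), 384 (doxycycline), 136 (chloramphenicol), 1019 (DNP), 301 (rotenone), 1496 (antimycin A), 581 (FK866), 190 (BPTES), 13 (rotenone against antimycin A), 69 (doxycycline against chloramphenicol) and 6 (rotenone against metformin). With array weights, the number of gene lists past the threshold was 11 (doxycycline), 6 (antimycin A), 10 (metformin) and 6 (FK866). With an estimated correlation between genes, the number of gene lists past the threshold was 2 (UK-5099), 0 (doxycycline), 2 (chloramphenicol), 6 (DNP), 2 (rotenone), 1 (antimycin A), 1 (metformin), 1 (etomoxir), 0 (FK866), 11 (tunicamycin) and 1 (BPTES). With the DMSO libraries split, r was 0.48 (antimycin A and etomoxir), 0.448 (metformin and etomoxir) and 0.422 (antimycin A and metformin). By edgeR on the recovered reads, the number of genes changed was 106 (rotenone), 4 (rotenone against antimycin A) and 4 (rotenone against metformin). Without DMSO replicates 1 and 2, the number of genes changed was 206 (UK-5099) and 62 (rotenone).

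Setting aside the 6 libraries, the number of genes changed was 683 (UK-5099), 412 (doxycycline), 83 (chloramphenicol), 817 (DNP), 133 (rotenone), 548 (FK866), 3993 (tunicamycin), 179 (BPTES), 15 (rotenone against antimycin A), 106 (doxycycline against chloramphenicol) and 11 (rotenone against metformin). Setting aside the 6 libraries, the number of gene lists past the threshold was 14 (doxycycline), 9 (antimycin A), 11 (metformin) and 11 (etomoxir). Setting aside the 6 libraries, r was 0.762 (antimycin A and etomoxir), 0.735 (metformin and etomoxir) and 0.701 (antimycin A and metformin). By edgeR with the 6 aside, the number of genes changed was 687 (UK-5099), 452 (doxycycline), 105 (chloramphenicol), 867 (DNP), 186 (rotenone), 599 (FK866), 3981 (tunicamycin), 197 (BPTES), 16 (rotenone against antimycin A), 117 (doxycycline against chloramphenicol) and 13 (rotenone against metformin). Without DMSO replicates 1 and 2 and with the 6 aside, the number of genes changed was 71 (chloramphenicol), 109 (rotenone), 159 (BPTES), 15 (rotenone against antimycin A), 101 (doxycycline against chloramphenicol) and 10 (rotenone against metformin). With the 6 aside and an estimated correlation, the number of gene lists past the threshold was 5 (antimycin A), 4 (etomoxir) and 2 (FK866). After GC correction, the number of genes changed was 44 (doxycycline), 6 (rotenone), 175 (antimycin A), 40 (metformin), 192 (etomoxir) and 86 (FK866). After GC correction, r was 0.654 (antimycin A and etomoxir), 0.663 (metformin and etomoxir) and 0.613 (antimycin A and metformin). After GC correction with the replicate block, the number of genes changed was 51 (doxycycline), 12 (rotenone), 202 (antimycin A), 47 (metformin), 195 (etomoxir) and 97 (FK866). With the second loess setting, the number of genes changed was 30 (doxycycline), 6 (rotenone), 163 (antimycin A), 39 (metformin), 160 (etomoxir), 83 (FK866) and 2 (rotenone against metformin). After GC correction with an estimated correlation, the number of gene lists past the threshold was 1 (UK-5099), 1 (doxycycline), 1 (chloramphenicol), 6 (DNP), 1 (rotenone), 1 (antimycin A), 1 (metformin), 2 (etomoxir), 0 (FK866), 10 (tunicamycin) and 3 (BPTES). With the 6 aside and GC correction, the number of genes changed was 709 (UK-5099), 75 (chloramphenicol), 215 (antimycin A), 77 (metformin), 291 (etomoxir), 77 (FK866), 3974 (tunicamycin), 185 (BPTES), 8 (rotenone against antimycin A), 116 (doxycycline against chloramphenicol) and 10 (rotenone against metformin). In that setting it was 158 (doxycycline), 700 (DNP) and 53 (rotenone). With the 6 aside and GC correction, the number of gene lists past the threshold was 11 (doxycycline), 5 (antimycin A) and 8 (FK866). With the 6 aside and the second loess setting, the number of genes changed was 703 (UK-5099), 150 (doxycycline), 80 (chloramphenicol), 211 (antimycin A), 82 (metformin), 272 (etomoxir), 75 (FK866), 4013 (tunicamycin), 189 (BPTES), 9 (rotenone against antimycin A), 112 (doxycycline against chloramphenicol) and 10 (rotenone against metformin). With the 6 aside, GC correction and an estimated correlation, the number of gene lists past the threshold was 3 (chloramphenicol), 4 (antimycin A), 3 (metformin) and 0 (FK866).

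Without each replicate number in turn, genes changed were 216 to 368 (UK-5099), 73 to 166 (doxycycline), 213 to 628 (DNP), 4 to 164 (rotenone), 583 to 907 (antimycin A), 211 to 667 (metformin), 586 to 856 (etomoxir), 119 to 419 (FK866), 1608 to 2969 (tunicamycin), 6 to 59 (BPTES), 0 to 8 (rotenone against antimycin A) and 0 to 2 (rotenone against metformin). Lists past the threshold were 3 to 11 (UK-5099), 2 to 7 (antimycin A), 2 to 6 (etomoxir), 4 to 16 (FK866) and 6 to 16 (BPTES). The r of treatments was 0.755 to 0.775 (antimycin A and etomoxir), 0.725 to 0.782 (metformin and etomoxir) and 0.693 to 0.743 (antimycin A and metformin).

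The direction of these log2 changes against DMSO, called as higher with all libraries as labelled, turned in the GC settings (correction alone, with the replicate block, with the 6 aside, with the second loess setting, or with both), where the values of each gene were: MRPL41 was at -0.085 with DNP, -0.22 and -0.16 with antimycin A, -0.10 and -0.15 with metformin, -0.078 and -0.032 with etomoxir and -0.002, -0.088 and -0.083 with FK866. CYC1 was at -0.10, -0.063, -0.11 and -0.064 with antimycin A, -0.049, -0.096, -0.053 and -0.10 with metformin and -0.06, -0.034, -0.066 and -0.037 with etomoxir. RPS15 was at -0.003 and -0.01 with antimycin A and -0.055, -0.072, -0.052 and -0.067 with metformin. ALDOA was at -0.054, -0.025, -0.033 and -0.004 with antimycin A and -0.018 and -0.014 with etomoxir. ECI1 was at -0.069, -0.04, -0.12 and -0.088 with antimycin A and -0.047 and -0.041 with etomoxir. HSPB1 was at -0.074, -0.054, -0.12 and -0.091 with antimycin A and -0.012, -0.021 and -0.046 with metformin. AEN was at -0.023, -0.03, -0.01 and -0.016 with metformin and -0.047, -0.04, -0.033 and -0.025 with etomoxir. AXL was at -0.065, -0.063, -0.04 and -0.035 with metformin. RPL36 was at -0.081, -0.085, -0.092 and -0.093 with etomoxir. MYL9 was at -0.065, -0.046, -0.048 and -0.027 with etomoxir. HMOX1, at 0.01 ± 0.09, adjusted p = 0.98 with metformin as labelled, was called as lower with the 6 aside and GC corrected, at -0.35, and at -0.33 with the second loess setting as well. With quantile normalization FN1 was at 0 with DNP. The GC correction removes any trend with GC content, so this is its own construction, and the cause of the trend was not tested.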

Other observations

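The test of tubulin mRNAs was chosen only after the results were seen, as were the genes named here for their values. CDKN1A rose with UK-5099, chloramphenicol, rotenone, antimycin A, metformin, etomoxir, FK866, tunicamycin and BPTES, from 0.23 ± 0.07 with metformin to 0.49 ± 0.07 with tunicamycin, and was at 0.10 ± 0.07, adjusted p = 0.562 with doxycycline and 0.06 ± 0.07, adjusted p = 0.756 with DNP; after GC correction it was called with UK-5099 and tunicamycin. KLF2 fell with UK-5099, at -1.61 ± 0.47, and rose with etomoxir, at 2.23 ± 0.47, and was not called after GC correction. With DNP, cholesterol synthesis and uptake genes fell in 1 of 25 (6 adjusted over the list alone). By camera the list gave adjusted p = 0.00359, and adjusted p = 0.0258 with an estimated correlation.

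Nuclear genes of complexes II to V fell with tunicamycin in 19 of 38 (23 adjusted over the list alone) (camera adjusted p = 3.28e-08, and adjusted p = 0.0399 with an estimated correlation) and cytosolic ribosomal protein genes in 24 of 82 (27 adjusted over the list alone). For that list camera gave adjusted p = 1.64e-06, and adjusted p = 0.291 with an estimated correlation. The list of 24 genes of the tricarboxylic acid cycle and pyruvate entry did not pass the threshold in any comparison (lowest camera adjusted p = 0.0937), nor did the NAD synthesis list (lowest 0.261). Mitochondrial chaperones and proteases passed with BPTES, with 0 of 17 called as higher. As a set they gave a camera adjusted p = 0.0168, and adjusted p = 0.0627 with an estimated correlation. Fatty acid synthesis genes rose in 2 of 12 (3 adjusted over the list alone) with FK866 as labelled, which includes replicate 6, nearest to tunicamycin. The set test (camera) gave adjusted p = 0.0155, and adjusted p = 0.098 with an estimated correlation. Of the markers of other skin cells, KRT10 of keratinocytes, MITF of melanocytes, CD68 and CD163 of macrophages and VWF, KDR and ESAM of endothelium were measurable. Against DMSO, CD163 was the marker called, at 2.54 ± 0.73 with antimycin A (10.2 against 0.48 normalised counts) and 2.69 ± 0.73 with FK866 (22.8 normalised counts). These are low values, and both groups hold a library set aside above. The FK866 mean lies above what its log2 change gives, so few libraries may hold most of it.

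The values of tubulin mRNAs tended to be lower with rotenone. Rotenone binds tubulin, and cells lower tubulin mRNAs when free tubulin rises, so a hypothesis is that this may be an effect of rotenone on microtubules. Of 8 tubulin genes, 8 were lower than in DMSO, with a median log2 change of -0.228 (camera p = 2.56e-05, and p = 0.0568 with an estimated correlation), and 0 were called by limma with all libraries as labelled. TUBB3, TUBB4B and TUBB6 lay within 1 standard error of no change there, at -0.065 ± 0.103, -0.03 ± 0.118 and -0.074 ± 0.096. Against metformin, as labelled, they were at -0.426, -0.267 and -0.308. With the 6 libraries set aside, the median against DMSO was -0.228 with 4 of 8 called, and against metformin, another complex I inhibitor, -0.328 with 6 of 8 called. Lower tubulin values prompted the hypothesis, so these medians do not test it independently, and the hypothesis stays open. After GC correction as well the median against metformin was -0.312 over 7 genes, which argues against a GC trend as the whole cause. The list was widened to 8 genes after a result with fewer of them had been seen. The comparisons share the rotenone libraries and are not independent, and toxicity to microtubules was not measured.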
